A study of Danio rerio with 15 samples.

How the data were processed

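The series holds 15 RNA-seq libraries from whole wild-type (AB strain) zebrafish larvae at 120 hours post-fertilization. Larvae were untreated controls or were exposed to perfluorooctanesulfonic acid (PFOS), a persistent fluorinated surfactant, at 0.1, 1, 5 or 10 µM, with 3 libraries per group. Per the labels' protocols, RNA was extracted with RNAzol and sequencing libraries were quantified with a KAPA kit. The labels do not say whether the 3 libraries of a group came from separate clutches or exposures, so p-values measure the spread between these libraries, which may be partly technical.

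Estimated counts of reads per gene and per transcript were deposited as whole numbers, per the file headers, with Ensembl gene and transcript identifiers, symbols and coordinates. The gene values equal the sums of their transcripts only up to rounding, so they were treated as estimated counts and used as whole numbers. RPKM values (reads scaled to length and library total) were also deposited per the file headers and those of the 12 libraries matched to a sample were used only to recover the length each gene had been divided by. The aligner, the counting tool and the genome build are not given in the sources used here, nor is any use of strand. A further 18 per-sample columns of the gene table and 30 of the transcript table were not used. Control, 0.1, 1 and 5 µM columns matched sample titles by group and number. The 10 µM columns carry the numbers 2, 3 and 4 while the titles carry 1, 2 and 3, so these columns were assigned to the group only, are named here by the number in the column, and were never paired.

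Library totals ran from 11956657 to 19978125 estimated counts. Of 32520 genes in the table, 5419 were at 0 in every library and 21477 passed edgeR's filterByExpr. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with all 15 libraries in 1 model of 5 group means. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and tests were two-sided. All adjusted p-values for single genes in the text come from this edgeR model unless another tool is named. Standard errors (SE) of log2 fold changes were obtained by dividing the absolute log2 fold change by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD. The common dispersion was 0.0168, a coefficient of variation between libraries of about 13.0%.

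Comparisons were each dose against control, 10 µM against 5 µM, an F test over all 4 doses, and a slope over dose rank. A total of 48 gene lists (pathways, stress responses and tissue markers) were written before the data were examined, as were the tests, the alternatives listed first below and the rule for named genes. Of the symbols in the lists, 94.4% were found in the table, and 47 lists had at least 5 tested genes. The list of oestrogen targets and sex steroids was not among these 47. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with prior count 2), beside camera with an estimated correlation and fry. Fry was read for a shared direction unless stated.

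Named genes were the largest passing log2 fold changes (10 rises and 10 falls at 10 µM, 5 and 5 at 5 µM, 3 and 3 at 0.1 and 1 µM and between 10 and 5 µM). They also had a mean of at least 1 CPM in the higher group, all 3 exposed libraries on one side of all 3 reference libraries, and a symbol that is not clone-based. Accession-like symbols were treated as clone-based. Where a dose had no passing gene, the 3 smallest p-values were named. Up to 4 members of smallest p were taken from each list discussed, except for a gene that is not reported here, and 8 reference genes were fixed (cyp1a, elavl3, mbpa, gfap, vtg1, cyp7a1, fabp10a and angptl4). The symbols mmd2b, c6, cplx2, calm3a and cyp2y3 each belong to 2 tested genes, and the values given are for the gene picked by these rules. The gene vtg1 did not pass the filter on low counts and has no value here.

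The fit was tested on simulated counts with the real means, dispersions and library sizes, with 200 genes changed. For 10 µM against control, with 21302 genes tested, it recovered 29.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 87.9% of those changed 3-fold. For 5 µM, with 21258 genes tested, the shares were 31.3%, 65.7% and 89.4% for the same folds. For 1 µM they were 28.4%, 67.2% and 86.4% (21284 genes), and for 0.1 µM 23.9%, 67.2% and 86.4% (21296 genes). Unchanged genes called were 7 at 10 µM, 6 at 5 µM, 10 at 1 µM and 8 at 0.1 µM. The simulated libraries were independent and all groups shared 1 dispersion per gene, so similar shares across doses were built in. The real 5 µM libraries differed more from each other than those of 10 µM, so the 5 µM shares may be too high.

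Alternatives fixed in advance were DESeq2 size factors, no filter, a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0 as the tool, only the 2 groups compared, a fold change of at least 1.5, dose in µM, a replicate block, and leaving out each library. Alternatives added after the data were seen were 2, 3 or 4 surrogate variables (sva 3.50.0), replicate blocks over fewer groups, removal of each library's trend over gene length, and thinning to the smallest total. The settings tried on agreement between doses and, except for the set tests and block, on lists were also added later.

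Replicate numbers were checked by correlating deviations from group means across genes. Same-numbered libraries correlated at 0.437, 0.380 and 0.452 between control and 0.1 µM and at 0.336, 0.261 and 0.190 between control and 1 µM, so the title numbers pair these groups by that measure. The labels do not say what the numbers stand for. The 5 µM libraries did not meet this rule and the 10 µM columns carry no title numbers. No library pair of a group agreed within sampling noise. The lowest chi-square per gene was 3.02, between the 10 µM libraries numbered 2 and 4, where counting noise alone gives about 1. All other pairs within a group lay from 6.67 to 26.6, so these libraries were more alike than any other pair. Whether they were prepared separately is not given. Figures were drawn with matplotlib 3.10.9.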

Results

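Gene expression was measured by RNA-seq in whole zebrafish larvae at 120 hours post-fertilization, in 5 groups of 3 libraries: untreated controls and larvae exposed to 0.1, 1, 5 or 10 µM PFOS. The title of the series places the work in the study of developmental neurotoxicity. Total estimated counts were 13447347 to 15076888 in controls, 14122138 to 19978125 at 0.1 µM, 12203158 to 13467298 at 1 µM, 12960818 to 14516361 at 5 µM and 11956657 to 12858343 at 10 µM. Mitochondrial genes took 3.78% to 5.28% of counts, the highest share being in PFOS 5 µM replicate 3.

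**Figure D1:**
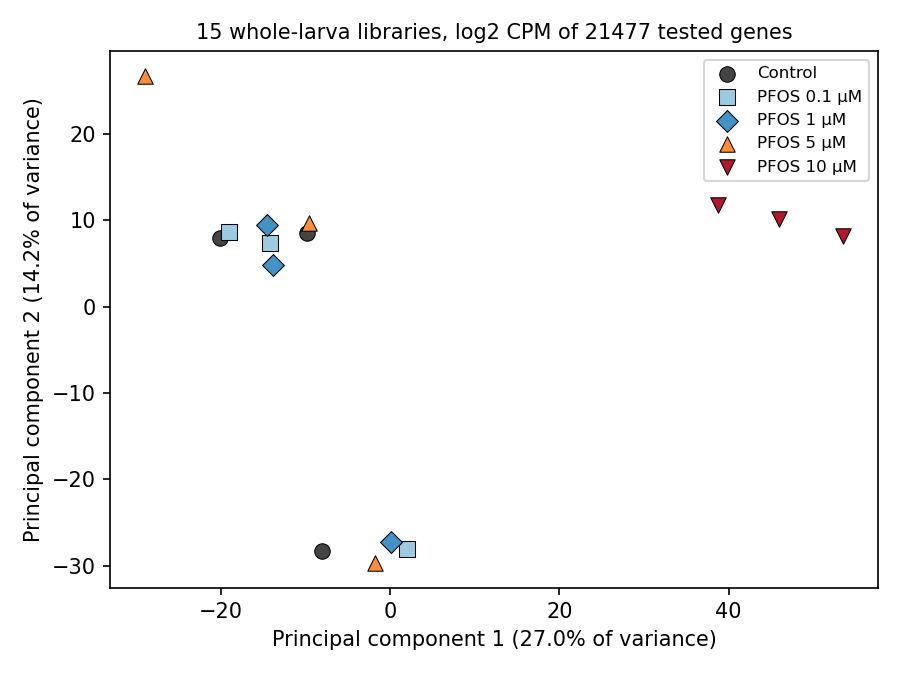
Each point is 1 library, placed by its scores on principal components 1 and 2 of log2 CPM (axes in component units, with the share of variance), and marker and colour give the group. The 3 libraries of 10 µM lie at 38.8 to 53.5 on component 1, while all other libraries lie below 2; component 2 sets the libraries numbered 1 of the other 4 groups apart from the rest.

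The comparison of 10 µM with control asked which genes differed at the highest dose. A total of 3098 of 21477 genes passed the threshold, 1670 higher and 1428 lower, and 1434 of them changed at least 1.5-fold. The insulin-like growth factor binding protein gene igfbp1b rose from 7.57 ± 2.19 to 67.0 ± 15.4 CPM (SD, n = 3 per group), a log2 fold change of 3.14 (SE 0.296, adjusted p = 4.52e-05). The complement gene c7b had the smallest adjusted p, 6.96e-06, and rose from 8.64 ± 0.626 to 48.8 ± 6.82 CPM. In the deposited coordinates, whose build is not given in the sources used here, igfbp1b lies on chromosome 2 from 124433 to 127945 and c7b on chromosome 21 from 20901505 to 20915291. The count without single libraries fell to 1707 without control replicate 1, 1362 without control replicate 3, 1047 without the 10 µM library numbered 2 and 1548 without that numbered 4. The 10 µM libraries shared no deviation pattern with other groups (correlations from -0.125 to 0.128), and no batch is given, so a batch and the dose cannot be told apart here.

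The largest rises at 10 µM were in jac9 (log2 fold change 4.96, SE 0.532), jac8 (3.79, SE 0.803), hspa12a.2 (3.78, SE 0.601), onecut2 (3.17, SE 0.605), igfbp1b, the ferritin-like gene fthl29 (2.99, SE 0.528), mmd2b (2.95, SE 0.797), the chemokine gene ccl34a.4 (2.80, SE 0.573), scpp8 (2.67, SE 0.622) and the natriuretic peptide gene nppb (2.60, SE 0.513). Of these 10, all but igfbp1b and fthl29 had a control mean below 1 CPM. The level of jac9 was 0.381 ± 0.0690 CPM in controls and 12.2 ± 5.63 CPM at 10 µM, whereas fthl29 went from 15.04 ± 3.448 to 119.5 ± 11.74 CPM. The largest falls were in the stanniocalcin-like gene stc1l (-6.05, SE 1.15), cyp2aa8 (-4.54, SE 0.636), itln2 (-3.53, SE 0.758), the hatching enzyme genes he1.2 (-3.43, SE 0.515) and he1.1 (-2.72, SE 0.540), sdr42e2 (-3.10, SE 0.579), cyp2aa4 (-2.94, SE 0.431), UBLCP1 (-2.92, SE 0.502), cyp2aa9 (-2.77, SE 0.542) and guca1d (-2.42, SE 0.661). The level of cyp2aa8, a cytochrome P450 gene, went from 43.4 ± 16.4 to 1.85 ± 0.648 CPM, and that of stc1l from 5.74 ± 2.27 to 0.0777 ± 0.0763 CPM. All 20 had an adjusted p of at most 0.0245. With libraries left out in turn, jac8 and scpp8 did not pass without the 10 µM library numbered 2, nor guca1d and mmd2b without that numbered 2 or 4 or control replicate 1, nor mmd2b without control replicate 2. Reads of the jac, cyp2aa, he1 and hspa12a families can be shared between near-identical copies, so the split between members is uncertain.

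**Figure D2:**
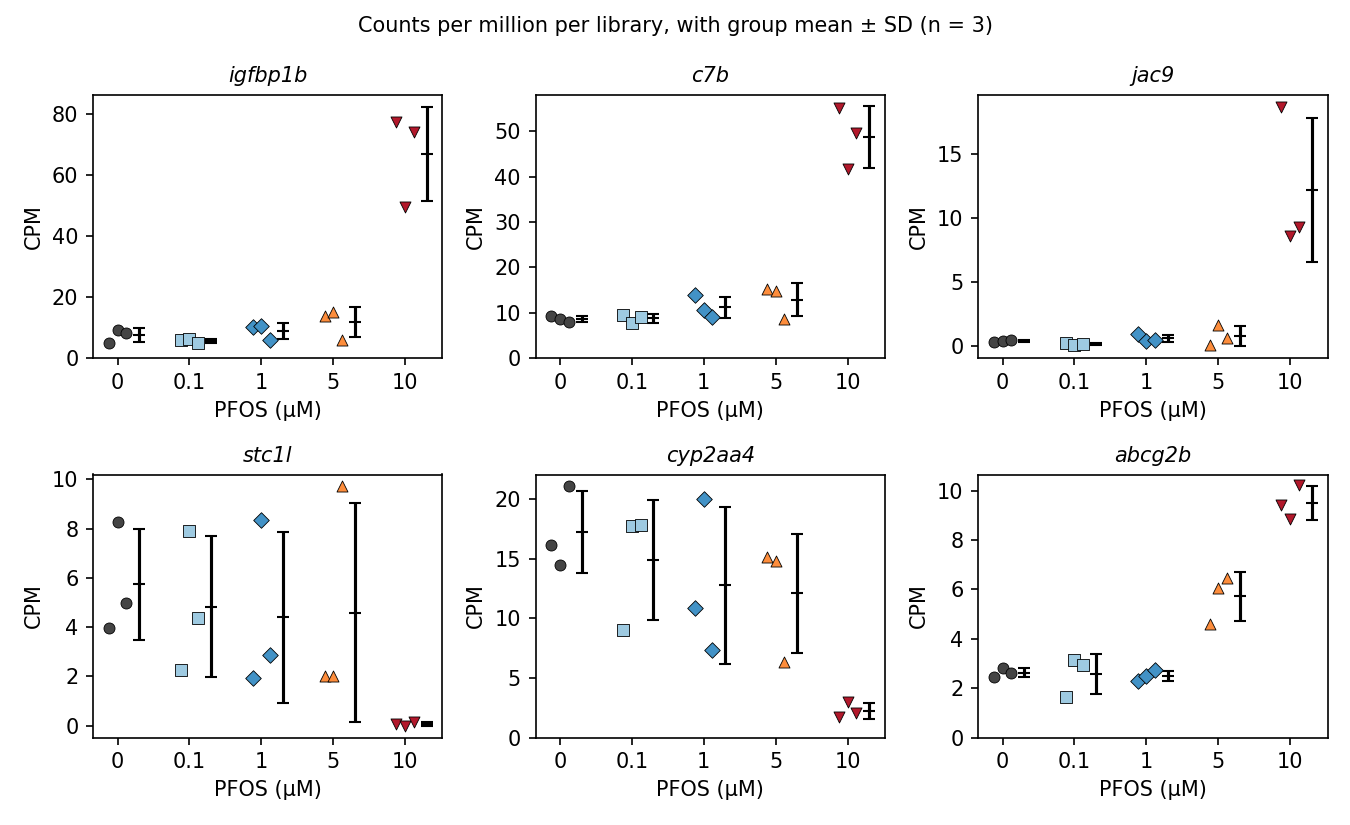
Points give the CPM of each library for 6 genes against PFOS concentration (µM, 0 for control, evenly spaced), and the bar beside them is the group mean ± SD (n = 3). The 10 µM libraries of igfbp1b lie between 49.4 and 77.5 CPM, above every other library, and abcg2b has a mean of 5.71 CPM at 5 µM and 9.50 CPM at 10 µM.

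Among lists fixed before the data were examined, 22 of 47 passed camera at 10 µM, 13 higher and 9 lower. Another split that mixed control and 10 µM libraries also called 22 lists. Such a split places the 10 µM libraries unequally on its sides and so keeps part of their difference from control. It therefore cannot show how many camera calls differences between single libraries alone would give. This stays unknown and limits all list results below. None passed with an estimated correlation (smallest adjusted p = 0.413 with an estimated correlation), while 13 also passed fry in the same direction. The 9 that did not pass fry (adjusted p from 0.0617 to 0.284) were oxidative phosphorylation, complement, leukocyte, ER stress, cholesterol, hepatocyte, corticosteroid, glutamate and GABA, and lens genes. Proteasome genes were higher: 22 of 40 rose and 0 fell (33 and 1 adjusted over the list alone, camera adjusted p = 2.51e-11), among them psmd11a (0.65, SE 0.0968), psmd3 (0.65) and psmc1b (0.51). Of 78 nuclear-encoded oxidative phosphorylation genes 22 rose and 0 fell (28 and 0 adjusted over the list alone), including ndufv3 (0.98) and atp5mf (0.75), but the median of this list went from 0.23 to 0.08 with each library's trend over gene length removed. In the hypoxia list 10 of 30 rose and 2 fell (11 and 2 adjusted over the list alone), with igfbp1b, igfbp1a (1.73), ndrg1b (1.1) and the oxygen-sensing hydroxylase gene egln3 (1.2). The inflammation list had 8 of 33 higher and 0 lower (9 and 0 adjusted over the list alone), with fosl1a (2.18), ptgs2b (1.65), which encodes a prostaglandin synthase, and cxcl8b.1 (2.14). The complement and acute phase list had 10 of 30 higher and 0 lower (11 and 0 adjusted over the list alone), with lect2l (1.94), c1r (2.42) and c6 (0.71). Leukocyte markers also passed, with 4 of 31 higher and 0 lower (4 and 0 adjusted over the list alone), led by marco (1.41), but not without control replicate 3 (adjusted p = 0.0715), and their median went from 0.29 to 0.17 with the length trend removed.

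Stress lists and cholesterol synthesis were higher as well. The other lipid lists did not pass camera: fatty acid oxidation had 4 of 28 higher and 2 lower (adjusted p = 0.565), lipogenesis 1 of 16 higher and 0 lower (adjusted p = 0.274) and plasma lipid transport 6 of 21 higher and 2 lower (adjusted p = 0.226). Of 26 NRF2 and oxidative stress genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with keap1b (0.69) and nqo1 (0.65), which did not pass without control replicate 3 or the 10 µM library numbered 2 or 4. Of 29 ER stress genes 9 rose and 1, phgdh (-0.66), fell (14 and 2 adjusted over the list alone). Of 19 heat shock genes 7 rose, with hspb9 at 2.04, and 1, hsp90aa1.1 (-1.03), fell (9 and 2 adjusted over the list alone); the list did not pass without control replicate 3 (adjusted p = 0.0627). The p53 list had 6 of 22 higher and 0 lower (7 and 0 adjusted over the list alone), with pmaip1 (1.11) and gadd45aa (0.98), and did not pass without the 10 µM library numbered 4 (adjusted p = 0.0598). Cholesterol synthesis had 5 of 25 higher and 0 lower (6 and 0 adjusted over the list alone), with hmgcs1 (0.93), insig1 (0.71) and ldlra (0.57). The call of insig1 was lost without the 10 µM library numbered 2 or 4, and that of ldlra on leaving out each of the 10 µM libraries or control replicate 2 or 3. Hepatocyte markers had 7 of 31 higher and 0 lower (8 and 1 adjusted over the list alone), with agxtb (1.1), tdo2b (1.04) and fabp10a (0.65), the last of which did not pass without control replicate 3, and their median went from 0.22 to 0.13 with the length trend removed. The corticosteroid list passed camera at an adjusted p of 0.0404, with 4 of 20 higher and 1 lower (4 and 1 adjusted over the list alone). It passed in 5 of 9 settings of scaling, filter and libraries, and not with the stricter filter or without control replicates 2 or 3 or the 10 µM library numbered 2 (adjusted p up to 0.0856). With an estimated correlation the adjusted p of the 7 lists of this group that passed was 0.471 to 0.684.

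Several neural and structural lists were lower at 10 µM, while the monoamine and cholinergic list (1 of 37 higher and 7 lower, camera adjusted p = 0.0654) and hair cell genes (0 of 29 higher and 2 lower, adjusted p = 0.226) did not pass camera. Fry called the monoamine and cholinergic list lower (adjusted p = 0.0275), and it passed camera in 4 of 9 settings of scaling, filter and libraries. Of 38 pan-neuronal and synaptic genes 13 fell and 0 rose (15 and 0 adjusted over the list alone, camera adjusted p = 2.69e-06, median log2 fold change -0.23), led by the tubulin gene tuba1c (-0.62, SE 0.124), inaa (-0.44), cplx2 (-0.44) and tubb5 (-0.55), the last of which did not pass without control replicate 1 or the 10 µM library numbered 2. In the glutamate and GABA list 8 of 42 fell and 3 rose (11 and 4 adjusted over the list alone), with the transporter gene slc1a2a (-0.56) and the receptor gene gabrb2a (-0.42) lower and glula (0.61), encoding a glutamine synthetase, higher. In the neurogenesis list 4 of 32 fell and 0 rose (5 and 0 adjusted over the list alone), namely pax6a (-0.44), dla (-0.47), dlb (-0.60) and sox3 (-0.40). Of these, sox3 (adjusted p = 0.0483) did not pass in 10 of 16 settings, among them the omission of each control and each 10 µM library. The calls of dla and dlb were lost without control replicate 1 or 2 or the 10 µM library numbered 2, and that of dlb also without the 10 µM library numbered 4. Cartilage and bone genes were the list with the lowest median, -0.44: 16 of 31 fell and 1 rose (19 and 3 adjusted over the list alone), with matn4 (-0.71), phex (-0.62) and col9a1a (-0.72). Of 45 skeletal muscle genes 16 fell and 0 rose (17 and 3 adjusted over the list alone), with ttn.1 (-0.64), which went from 2391 ± 85.2 to 1530 ± 47.9 CPM, and actn3a (-0.68). Calcium handling had 12 of 42 lower and 2 higher (14 and 2 adjusted over the list alone), with casq1a (-1.09) and calm3a (-0.75). Pigment cell genes had 9 of 24 lower and 0 higher (10 and 1 adjusted over the list alone), with pnp4a (-1.30) and paics (-1.89). The retinoid cycle had 5 of 25 lower and 1 higher (8 and 1 adjusted over the list alone), with stra6 (-0.68), rlbp1b (-0.69) and rpe65a (-0.57), and did not pass with the stricter filter (adjusted p = 0.0573). Lens crystallins had 3 of 31 lower and 0 higher (2 lower and 0 higher adjusted over the list alone). They passed in 5 of 9 settings, and not with the stricter filter or without control replicates 1 or 3 or the 10 µM library numbered 4 (adjusted p up to 0.116). With an estimated correlation the adjusted p of the 9 lists that passed as lower was 0.413 to 0.780.

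**Figure D3:**
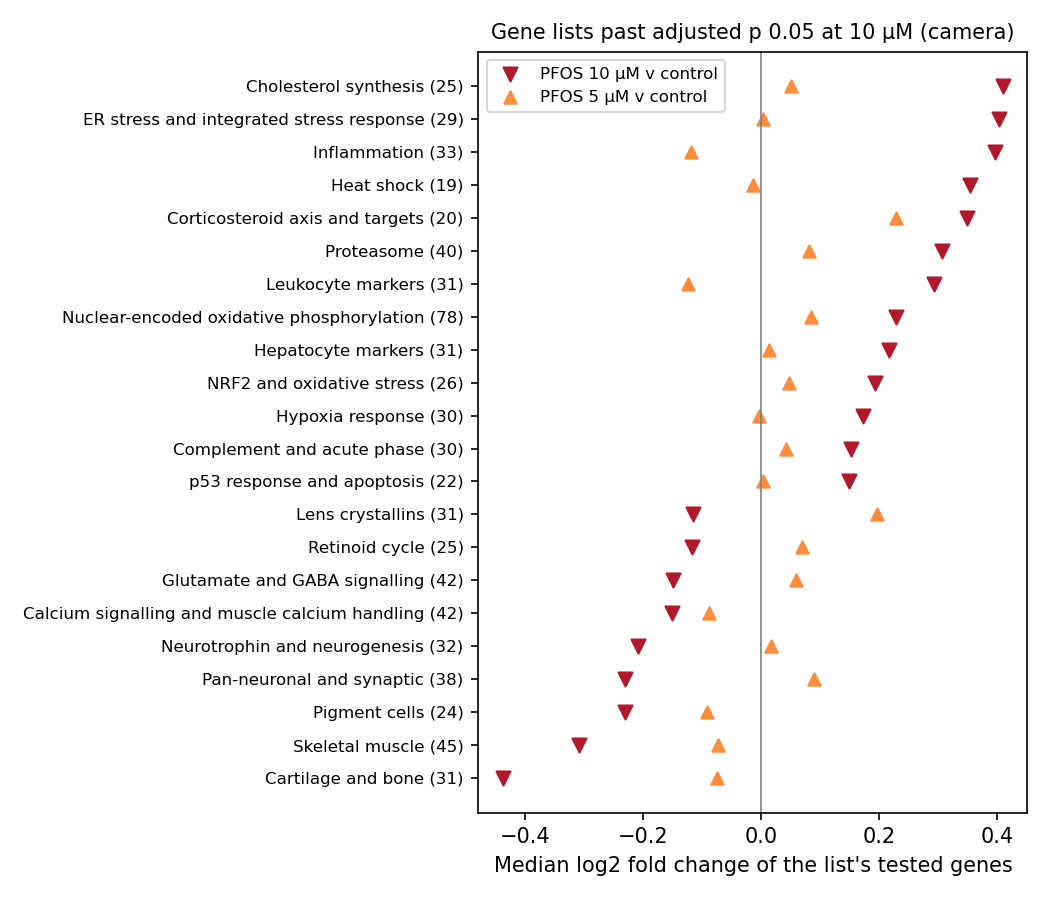
Each row is a list that passed camera at 10 µM, with its number of tested genes, and the points give the median log2 fold change of its genes against control at 10 µM (red) and 5 µM (orange). The pan-neuronal list has a median of -0.23 at 10 µM and 0.09 at 5 µM.

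Of the reference genes at 10 µM, cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, fell (-0.71, SE 0.187, adjusted p = 0.0205) and the liver fatty acid binding protein gene fabp10a rose (0.65, SE 0.150, adjusted p = 0.0105). The call of cyp7a1 was lost in 5 of 16 settings (adjusted p up to 0.0954), among them without control replicate 1 or 3 or the 10 µM library numbered 2 or 3. That of fabp10a was lost in 4, among them with the length trend removed and without control replicate 3. The others did not pass: cyp1a was at -0.09, the neuronal gene elavl3 at -0.22 (adjusted p = 0.166), mbpa at -0.02, gfap at -0.25 and angptl4 at 0.20. Erythroid genes had 0 of 25 past the threshold. The AHR target list had 1 higher and 1 lower of 9, and glia and myelin genes 1 and 1 of 22, and neither list passed camera.

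The transcript table gave 2016 of 32275 transcripts past the threshold at 10 µM, 1005 higher and 1011 lower. They belonged to 1910 genes, of which 248 had not passed as genes, and 18 genes had both a higher and a lower transcript. Some of these rest on very large log2 fold changes of 1 transcript, as in rpl28 (13.1), dstyk (10.8) and vcp (-9.54). Others were moderate, as in atp8a2 (0.367 and -0.613). Counts per transcript are estimates, and the test leaves out the uncertainty of sharing reads between transcripts. Whether transcript use changed was not tested. The count ranged from 312 without the 10 µM library numbered 2 to 1899 without that numbered 3. It was 619 without control replicate 1, 1295 without control replicate 2, 490 without control replicate 3 and 691 without the 10 µM library numbered 4.

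At 5 µM, 0 of 21477 genes passed in edgeR, with 837 at an unadjusted p under 0.05, and 12 passed in DESeq2. The 837 are below the share of 0.05 that chance alone would give, but this depended on the setting. The count was above that share without 5 µM replicate 2 (1648 of 21732) and with the replicate block over 12 libraries (1099 of 21314). It was also above with 2, 3 or 4 surrogate variables (1482, 1474 and 1613 of 21477). In the other settings tried it stayed below, as without 5 µM replicate 1 (990 of 21722) or replicate 3 (924 of 21714). The 3 genes of smallest p, none passing, were the bile salt export pump gene abcb11b (log2 fold change 0.85, SE 0.125, adjusted p = 0.0910), cyp2y3 (0.87, SE 0.158, adjusted p = 0.347) and the efflux transporter gene abcg2b (1.12, SE 0.213, adjusted p = 0.347). The level of abcb11b was 28.4 ± 1.51 CPM in controls and 51.2 ± 3.98 CPM at 5 µM. Without the filter on low counts abcb11b alone passed. Reference genes did not pass, with cyp1a at 0.24, elavl3 at 0.10, mbpa at 0.23, gfap at 0.22, cyp7a1 at 0.12, fabp10a at 0.50 and angptl4 at 0.00467. Camera called 21 lists, 15 higher and 6 lower, and 0 with an estimated correlation (smallest adjusted p = 0.295 with an estimated correlation) or with fry for a shared direction. Fry for change in either direction passed for the bile acid list (adjusted p = 3.39e-07) and other xenobiotic metabolism (adjusted p = 0.0122). In the latter, 0 of 31 genes passed, or 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.28e-08, and 0.295 with an estimated correlation). PFOS 5 µM replicate 3 stood apart from its group, and without it the called lists were 19 higher and 0 lower. They were 7 higher and 10 lower without 5 µM replicate 1, and 16 and 9 without replicate 2. Called by camera the opposite way to 10 µM were the pan-neuronal (median 0.09, adjusted p = 0.00051), retinoid cycle (adjusted p = 0.0115) and lens (median 0.20, adjusted p = 1.2e-12) lists, higher at 5 µM, and the inflammation (adjusted p = 0.0115) and leukocyte (adjusted p = 0.0375) lists, lower at 5 µM. Neither of these lower calls held without PFOS 5 µM replicate 3, where no list was called lower. Other lists were called by camera the same way at both doses. Higher at both were proteasome (adjusted p = 0.00193 at 5 µM), nuclear-encoded oxidative phosphorylation (adjusted p = 1.64e-06) and cholesterol synthesis (adjusted p = 0.0248). Lower at both was calcium handling (adjusted p = 0.0099 at 5 µM), a call also lost without 5 µM replicate 3.

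At 1 µM and 0.1 µM, 0 genes passed in edgeR and 0 in DESeq2, with 422 and 243 genes at an unadjusted p under 0.05 in edgeR. Both counts are below the share of 0.05 that chance alone would give, so they do not by themselves point to changed genes. The fit has no replicate block, so differences between the paired numbers stay in its spread and make it strict. With the block over control, 0.1 and 1 µM the counts were 995 and 599, still below that share. At 1 µM the smallest p-values, all with an adjusted p of 1, belonged to si:ch73-236c18.5 (1.54, SE 0.363), cgref1 (0.71, SE 0.177) and si:ch73-14h1.2 (-0.92, SE 0.232). At 0.1 µM they belonged to si:ch73-366i20.1 (1.5, SE 0.381), cd28l (-0.76, SE 0.198) and the serotonin receptor gene htr7a (1.44, SE 0.375), also with an adjusted p of 1. Reference genes at 1 µM lay between -0.23 for angptl4 and 0.32 for fabp10a, with cyp1a at 0.13, elavl3 at 0.02, mbpa at -0.01, gfap at -0.02 and cyp7a1 at -0.16. At 0.1 µM they lay between -0.19 for cyp7a1 and 0.09 for elavl3, with cyp1a at 0.01, mbpa at 0.00925, gfap at 0.07, fabp10a at -0.12 and angptl4 at -0.09. With the replicate block and only the 2 groups compared, 3 genes passed at 1 µM and 7 at 0.1 µM. With the block over control, 0.1 and 1 µM, 1 passed at 1 µM, zgc:111983, and 0 at 0.1 µM. Camera called 9 lists at 1 µM and 2 at 0.1 µM, and 0 at either dose with an estimated correlation (smallest adjusted p = 0.989 and 0.972 with an estimated correlation).

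Between 10 and 5 µM, 3309 genes differed, 1732 higher and 1577 lower at 10 µM. The largest rises were in hspa12a.2 (4.67, SE 0.677), jac9 (3.99, SE 0.481) and KYAT3 (3.69, SE 0.955), and the largest falls in stc1l (-5.74, SE 1.18), cyp2aa8 (-3.85, SE 0.646) and itln2 (-2.93, SE 0.805). The call of KYAT3 was lost without 5 µM replicate 2 or the 10 µM library numbered 2 (adjusted p up to 0.0551), and that of itln2 without 5 µM replicate 1 or the 10 µM library numbered 2 or 4 (adjusted p up to 0.0991). Of 47 lists camera called 13 higher and 12 lower at 10 than at 5 µM, fry 8 and 13, and 0 were called with an estimated correlation (smallest adjusted p = 0.113). Among the higher lists were proteasome (14 of 40 genes higher, 0 lower; camera adjusted p = 1.54e-07) and inflammation (12 of 33 higher, 0 lower; camera adjusted p = 5.2e-07), and among the lower lists lens crystallins (18 of 31 lower, 0 higher; camera adjusted p = 1.49e-08). Other xenobiotic metabolism, called higher at 5 µM, had 14 of 31 lower and 4 higher (camera adjusted p = 0.000167). Of the pan-neuronal genes 20 of 38 were lower and 0 higher (camera adjusted p = 2.53e-10; adjusted p = 0.447 with an estimated correlation), and this list and the lens list were called higher than control at 5 µM. The count was 1575 without PFOS 5 µM replicate 3, 1092 without the 10 µM library numbered 2, 1821 without that numbered 4 and 1807 with only the 2 groups in the fit.

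The F test over all doses called 1697 genes and the slope over dose rank 770, of which 543 rose and 227 fell. Both rested on the 10 µM libraries: without those numbered 2, 3 and 4 in turn, the F test gave 186, 963 and 383 genes and the slope 24, 76 and 18. The slope count also moved to 432 without control replicate 1, 315 without control replicate 3, 287 and 252 without 0.1 µM replicates 2 and 3, 488 without 1 µM replicate 1, and 1159 and 2512 without 5 µM replicates 2 and 3.

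Log2 fold changes at 5 and 10 µM, both against the same controls, correlated across genes at r = 0.28 (Spearman 0.22). Genes are not independent replicates, and unchanged groups simulated against shared controls gave a mean r of 0.49. The covariance was 0.0330 against a simulated 0.0345. The simulated libraries were independent, whereas real controls and 5 µM libraries share deviations, so the comparison does not decide whether the doses share an effect. The 3 controls are too few to be split. No overlap of calls can be given because 5 µM had 0 in edgeR (837 at an unadjusted p under 0.05, and 12 in DESeq2).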

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

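The tests of library size, gene length and the 5 µM position below were chosen after the separation of the 10 µM libraries had been seen, though before their own results, and splits were grouped by pairs after their counts had been seen. The result marked for a closer look is the direct difference between the effects of 10 and 5 µM, 3309 genes by the test of the difference itself.

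The 10 µM libraries stood apart from all others, and no other split of the 6 libraries of 10 µM and control called a gene or transcript, though other splits called lists. With all libraries thinned to the smallest total 2932 genes were called at 10 µM, and 2919 with each library's trend over gene length removed, so neither a smaller depth nor a length trend accounts for the whole separation. The difference of the 5 µM libraries from those of 0.1 and 1 µM had a covariance of -0.000403 with the 10 µM change, and 45 of 84 choices of 3 of these 9 libraries gave as high a value (exact one-sided p = 0.536), the highest other, 0.0219, being the 3 libraries numbered 1. The 5 µM value combines 0.0133 and 0.00596 for replicates 1 and 2 with -0.0204 for replicate 3. The 0.1 and 1 µM libraries spanned at least as wide a range, from -0.0187 to 0.0160, so the 5 µM value decides nothing. A separate batch of the 10 µM libraries, a graded response to PFOS and a response that begins between 5 and 10 µM therefore cannot be told apart, since no batch is given and the 10 µM columns carry other numbers.

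Chance was examined with other splits of the libraries. The F test over all doses called 1697 genes, and 2 of 100 splits, the real one included, gave as many. For the slope over dose rank, with 770 genes, it was also 2 of 100. Splits were first limited to 40 for time, which gave 2 of 40 for both, a share on the threshold, and 100 were then drawn, the first 40 being the same. In both cases the other split as large (1939 and 1099 genes) was the only other draw that kept the 3 libraries of 10 µM in 1 group, and all draws that parted them gave at most 1 gene. By the share of 2 in 100, chance is a poor account of both counts. That share mainly measures how seldom a draw keeps the 3 libraries of 10 µM together, and the draws ignored the pairing of replicate numbers. Both counts reflect the separation of 1 group of libraries and do not show an order over doses.

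With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At 10 µM the real split called 3098 genes and 2016 transcripts and the highest other 0, with 1 split of 10 as large in each case. The difference between 10 and 5 µM gave 3309 against 0, also 1 of 10. At 0.1, 1 and 5 µM the real split and every other gave 0 genes, so 10 of 10 were as large. For lists, the real and highest other counts were 22 and 22 at 10 µM (2 of 10 as large), 21 and 28 at 5 µM (6 of 10), 9 and 20 at 1 µM (6 of 10), and 2 and 18 at 0.1 µM (10 of 10). At 0.1 µM the higher counts of other splits went with the replicate numbers, which pair this group with control, while at 1 µM the ranges overlapped. The cause was not tested. Of the 4 splits that part every pair, as the real one does, the highest other had 7 lists at 0.1 µM and 9 at 1 µM, and the 6 that do not had 11 to 18 and 7 to 20.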

How the results depend on the processing

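The surrogate-variable, length, depth and narrower block settings, those on agreement, and the scaling, filter and left-out-library settings on lists were chosen after seeing the data. Each cause was not tested unless the setting itself shows it. At 10 µM scaling, filters, DESeq2, thinning and length removal gave 2795 to 3076 genes, and 4042 with only the 2 groups. A 1.5-fold minimum left 1434 by its construction. With surrogate variables the count was 2992 with 2 (1599 higher, 1393 lower), 1943 with 3, the number estimated (897 and 1046), and 546 with 4 (173 and 373), so most were lower with 3 or 4. Of the 546, 343 were among the 3098; the cause was not tested, and such variables can absorb part of a group that stands apart. Leaving out each library gave 1047 to 2560 at 10 µM and 1092 to 3464 for 10 against 5 µM, where the 1.5-fold minimum gave 1493 and only the 2 groups 1807. At 5 µM the count of 0 became 1 without a filter, 12 with DESeq2, 1 (cyp2k18) with the replicate block over 12 libraries, and 16, 26 and 53 with 2, 3 and 4 surrogate variables. At 0.1 µM it became 1 with 3 or 4 surrogate variables (pcdh2ab11) and 7 with the replicate block on only the 2 groups; at 1 µM it became 3 with that block and 1 with the block over 9 libraries. Surrogate variables did not change 1 µM, nor did the planned block at 0.1 or 1 µM.

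The any-dose count was 2593 with DESeq2 and 186 to 2012 with a library left out. The slope gave 1352 with DESeq2, 3490 with dose in µM and 18 to 2512 with a library left out. Transcripts numbered 1329 without a filter and 312 to 1899 with a library left out. List counts were 0 with an estimated correlation at every dose, and with fry 0 at 0.1, 1 and 5 µM and 14 at 10 µM; with a library left out they ran from 4 to 8 at 0.1 µM and 4 to 11 at 1 µM. The planned block left them at 2, 9 and 21. The correlation between 5 and 10 µM was 0.415 without a filter and 0.180 to 0.410 with a library left out. Of 174 named genes passing at 10 µM, 52 passed under every setting and 122 were lost under at least 1; of 6 between 10 and 5 µM, 4 passed under every setting. Directions turned for mt-nd4l (-0.2346), rps29 (-0.06415) and mt-atp8 (-0.05753) with the length trend removed, and for mipa (0.07504) with 4 surrogate variables, none of them passing there. With the length trend removed, camera called 2 lists lower at 10 µM that it had placed higher without passing. Ribosomal proteins went from an adjusted p of 0.0678 (median 0.03) to 0.00176 (median -0.13), and mitochondrially encoded genes from 0.831 to 0.0319. Every list called at 10 µM kept its call and direction.

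No paired analysis was possible because the 10 µM columns carry no title numbers, for 10 µM, 10 against 5 µM, any dose, slope and transcripts. For 5 µM, same-numbered libraries correlated with controls at 0.346, -0.137 and -0.00167, so its numbers were not taken as pairs. Its replicates 2 and 3 correlated instead with control replicates 3 and 2 (0.277 and 0.222), so an exchange of these numbers stays open, and the 12-library block, which takes them as titled, is a check only. Most 1.5-fold changes were missed on simulated counts at the real depth; depth, spread and 3 libraries per group were not separated.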

Other observations

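The test of gene length on neuronal genes was written before its result was seen, and those of tissue share and clock genes were chosen after theirs.

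Single genes of the thyroid list, not described so far, passed at 10 µM while the list did not. The thyroid hormone receptor gene thrb fell (log2 fold change -0.77, SE 0.109, edgeR adjusted p = 0.000775), as did tg, encoding thyroglobulin (-0.90, adjusted p = 0.00581), which passed in all 16 settings tried. The deiodinase gene dio3b rose (1.28, SE 0.326), but did not pass without control replicate 1 or 3 or the 10 µM library numbered 2, nor with 4 surrogate variables. A lower duox (-1.63, adjusted p = 0.0480) was lost in 10 of 16 settings, among them the omission of each control and each 10 µM library. The thyroid list as a whole did not pass camera (adjusted p = 0.902), with 1 of 18 higher and 3 lower (3 and 3 adjusted over the list alone). Among transporters, abcg2b rose at 10 µM (1.85, SE 0.208) and differed between 10 and 5 µM (0.73, adjusted p = 0.0195), and abcb11b rose at 10 µM (0.71, SE 0.125). The phototransduction list had 11 of 53 lower and 2 higher without passing camera, with rcvrn3 (-1.05), grk7a (-0.92) and arr3b (-1.14) lower. Of 26 endothelial genes 3 rose, the scavenger receptor genes stab1 (0.71) and stab2 (0.62) and the lymphatic marker lyve1a (1.95), and 2 fell, one of them flt4 (-0.63). The endothelial list did not pass camera (adjusted p = 0.555), though like most lists it passed fry for change in either direction (adjusted p = 9.59e-12).

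Pan-neuronal genes were lower at 10 µM. Removing each library's trend over gene length left the list lower (camera adjusted p = 6.44e-06, with the test fixed on the unadjusted p, which is smaller still), which argues against length as the whole cause. A lower share of neural tissue stays open: 89.5% of the tested members lay below 0, but this restates the pattern and cannot separate it from lower expression per cell. Glia and myelin genes, with a median of -0.12 against control, did not pass camera, and the pan-neuronal list did not pass with an estimated correlation (adjusted p = 0.471). Against 5 µM, glia and myelin genes were lower at 10 µM (median -0.34, camera adjusted p = 0.00227, and 0.447 with an estimated correlation). Camera had called them higher than control at 5 µM (adjusted p = 0.00107). A separate batch of the 10 µM libraries also stays open.

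Of 34 clock genes 8 were lower and 2 higher at 10 µM, but the list did not pass camera (adjusted p = 0.205, and 0.780 with an estimated correlation). Collection at another time of day could give this if the 2 arms of the clock moved in opposite directions. The per and nr1d arm had a median of -0.32, with 7 of 21 lower, below the central 95% of random lists matched on expression (-0.16 to 0.12). The bmal and clock arm had a median of 0.2034, with 2 of 11 higher and 1 lower. This lay at the edge of its range of -0.2089 to 0.2042 (percentile 97.4), just inside it. The medians of the arms had opposite signs. Collection time therefore stays open and cannot be told apart from the dose, because the labels give no time of day.

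Genes that differed between replicate numbers overlapped slightly more with the genes called at 10 µM than independent lists would. In control, 0.1 and 1 µM, 1520 genes differed between numbers, of which 238 were called at 10 µM against 219 if the lists were independent. Over 12 libraries, with numbers taken as titled, 551 differed, of which 87 were called against 79.5. The fit has no replicate block, so such differences stay in its spread and make these genes harder to call. A batch of the 10 µM libraries alone need not involve these genes, so the overlap decides nothing about a batch.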
